A study of Mus musculus with 2 samples.

How the data were processed

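Nuclear RNA was measured by droplet single-nucleus sequencing (10x Genomics 3' chemistry, kit v3.1) in perivascular fat taken from around the mesenteric arteries of mice aged 11 weeks, per the labels' protocols. The tissue had been snap-frozen, homogenised, and its nuclei purified on an iodixanol gradient. There were 2 libraries, 1 from mice with floxed Prdm16 alleles (flox control) and 1 from floxed mice that also carried Cre recombinase under the Adipoq promoter (Prdm16 cKO). The labels do not say how many animals were pooled in a library. The series title names thoracic and abdominal perivascular fat and its design text names total RNA, whereas the labels of both samples name mesenteric fat and nuclear RNA, and the sample labels were followed.

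The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and nucleus barcode, not normalised, made with Cell Ranger 6.1.2 per the file headers and the submitters' processing notes. The genome build was mm10, per the submitters' processing notes. The annotation release, whether intronic reads were counted, and the filter that chose the barcodes are not given in the sources used here. Both libraries list the same 32285 genes by identifier and symbol. Positions were taken from GENCODE release M21 on GRCm38, the assembly behind mm10, are 1-based, and were found for 32235 of the 32285 identifiers. Counts of genes that overlap or run antisense to one another are uncertain, since the handling of strand is not given.

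The flox control library held 12060 barcodes with 108987031 UMIs and the library labelled Prdm16 cKO held 8086 barcodes with 70895490 UMIs. Nuclei were kept with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs. No barcode fell below either minimum, and 449 control and 217 cKO-labelled barcodes were removed for mitochondrial UMIs. Scrublet (scanpy 1.11.5) was run on each library. Its automatic threshold marked 0.01% and 0% of nuclei, under the preset minimum of 0.5%, so the nuclei with the highest scores were removed at the preset rate of 0.8% per 1000 nuclei. That took out 1079 of 11611 control nuclei and 495 of 7869 cKO-labelled nuclei.

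Kept nuclei of both libraries were clustered together in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0). Counts were scaled to a common total per nucleus and log-transformed, 2000 variable genes were chosen with both libraries weighing the same, and 30 principal components, 20 neighbours and a shared-neighbour graph were used without batch integration. The Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 gave 25 clusters. The deposited files used here hold no cell annotation, so clusters were named from 20 sets of markers. A name needed at least 3 markers of the set detected in 5% of the nuclei of the cluster at 2 times the mean of the other clusters, and no other set with more members among the 10 leading genes. Names carry the ending "-like", and a difference from any other account of these nuclei may come from these rebuilt names. Where 1 library gives most of a cluster, the cluster may be that library and not a type.

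The genes that defined the clusters were as follows. Adipocyte-like clusters were 0 (Slc1a3, Nrg4, Prkar2b), 1 (Elovl6, Acly, Acss2, Me1, Pgm3, Ppp1r3b, Dipk1b, Acaca, Prune2), 2 (Nnat, Tshr, Npr3, Pck1, Peg3) and 7 (Slc1a3, Adrb3, Nnat). Progenitor or fibroblast-like clusters were 3 (Gfpt2, Col14a1) and 14 (Nkain3, Itgbl1). Macrophage-like clusters were 4 (F13a1, Cd163, Mrc1) and 24 (Padi4, Prg4, Msr1). Mesothelial-like clusters were 6 (Vat1l, Ctnnd2, Wt1) and 9 (Muc16, Rbfox1), and vascular endothelial-like clusters were 10 (Adgrl4, Cdh13, Flt1) and 18 (Vwf, Ptprb). T cell-like cluster 8 was led by Themis and Lef1, lymphatic endothelial-like cluster 11 by Reln, Mmrn1 and Prox1, B cell-like cluster 12 by Pax5 and Bank1, and dendritic-like cluster 13 by Ndnf, Fcrls and Clec9a. Classes too small to compare were led by Il1rl1 and Gata3 (natural killer or innate lymphoid-like, 15), Cela1 and Cpb1 (pancreatic acinar-like, 17), Abcc9 and Notch3 (pericyte-like, 19), Sis and Muc2 (intestinal epithelial-like, 20 and 23), Myh11 and Acta2 (smooth muscle-like, 21) and Cdh19 (Schwann-like, 22). In clusters 5 (Lrp1b, Grik1) and 16 (Cd24a, Ccr3, Retnlg) the set that scored best had under 3 markers, so they stayed unnamed. In adipocyte-like nuclei, the control library lay mostly in clusters 0 and 2 and the cKO-labelled library mostly in clusters 0 and 1, so adipocyte values were also computed within each of the 4 clusters.

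Raw counts were summed per class and library, and classes with at least 100 nuclei in each library were compared: 9 classes in all. Levels are counts scaled to CPM by the total UMIs of the class in the library, with exact 95% Poisson intervals. The log2 ratio of the cKO-labelled library over the control has an exact conditional binomial interval, and shares of nuclei have exact Clopper-Pearson intervals. A count of 0 was taken to allow up to 3 counts. All intervals cover counting error only. With 1 library per genotype and no replicates, no difference has a replicate check, and no test, p-value, standard error or number of changed genes was computed, since nuclei are not replicates.

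The values within single adipocyte-like clusters were added after the data were seen. The filters of nuclei, the doublet rule, the marker sets, the clustering resolution and the size limit of classes were fixed before the data were examined. So were the measures and their intervals, the gene lists and the rule for naming genes. The rule always named Prdm16, Ucp1, Cidea, Adipoq, Lep, Agt and Qsox1 in adipocyte-like nuclei and Agtr1a in smooth muscle-like nuclei. In each compared class it further took genes with at least 50 UMIs over both libraries, a CPM of at least 20 in 1 library, and an interval of the ratio wholly above 1.5 or below its inverse. It left out mitochondrial, ribosomal protein and haemoglobin genes, receptor segments, unnamed gene models, sex-linked genes, and genes whose CPM was over 5 times higher in another class of the same library. The 12 highest and 12 lowest log2 ratios were named in adipocyte-like nuclei and the 5 highest and 5 lowest elsewhere. Each of 32 gene lists was summarised by the median log2 ratio of its members with at least 20 UMIs, its percentile among 10000 random lists of the same size matched on mean expression in bins of 20 genes, and up to 2 of the highest and 2 of the lowest members with at least 50 UMIs. A percentile is a description of these libraries. A few genes that the rule took are not given in the text.

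Other classes carried adipocyte RNA, read from 6 adipocyte markers. After seeing the data, an adipocyte profile scaled to those markers was therefore subtracted from each of the 8 other classes, and for Agtr1a from pericyte-like nuclei, and genes at least as high in a class as in adipocyte-like nuclei were listed apart. List medians after subtraction leave out members with no counts left in 1 or both libraries. Counting intervals of medians and of subtracted values came from Poisson draws. The code was tested on simulated Poisson counts with known folds. These held no variation between nuclei or animals. Coverage near 95% therefore checks the code, not the spread of real class sums. The interval held the true ratio for 95.8% of 17414 unchanged genes in adipocyte-like nuclei and 96.1% of 11153 in vascular endothelial-like nuclei. For genes changed 1.5-fold, 2-fold and 4-fold it held for 95.5%, 89.6% and 93.9% of 66 to 67 genes in adipocyte-like nuclei and for 91.0%, 97.0% and 97.0% in vascular endothelial-like nuclei. The size rule passed 100% of 67 genes changed 2-fold in adipocyte-like nuclei and 67.2% of 67 in vascular endothelial-like nuclei. It passed 98.5% of 66 genes changed 4-fold in vascular endothelial-like nuclei and 2.99% of 67 changed 1.5-fold in each.

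Alternatives were a minimum of 1000 UMIs, under 1% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2.0, each library clustered on its own, variable genes without list members, TMM scaling (edgeR 4.0.16 in R 4.3.3, scaling factors with no test), median-of-ratios scaling, the mean of CPM per nucleus, and nuclei thinned to 1000 UMIs. Further ones subtracted 5% or 10% of free RNA, took list members with at least 1 or 100 UMIs, and for Ucp1 used no thinning, 500 UMIs, or at least 2 UMIs. The scalings shifted the log2 ratios of a class by at most -0.087. Figures were drawn with matplotlib 3.10.9.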

Results

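Perivascular fat from around the mesenteric arteries of 11-week-old mice was profiled by single-nucleus RNA sequencing in 2 libraries, 1 of floxed control mice and 1 labelled Prdm16 cKO, in which Cre under the adiponectin promoter is meant to delete Prdm16 from adipocytes. The comparison asks how adipocytes and the cells around them differ when adipocytes lack Prdm16, a transcriptional regulator of the brown and beige fat programme. The control library gave 10532 kept nuclei with 92779065 UMIs and a median of 7035 UMIs and 2864 genes per nucleus. The library labelled Prdm16 cKO gave 7374 kept nuclei with 62275986 UMIs and a median of 6522 UMIs and 2793 genes. Each genotype had 1 library and there are no replicates, so every difference below compares these 2 libraries and has no replicate check, and every interval is a 95% interval of counting error only.

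Adipocyte-like nuclei were the most frequent class in both libraries, with 41.9% (41.0 to 42.9%) of 10532 control nuclei and 39.9% (38.8 to 41.0%) of 7374 cKO-labelled nuclei. Progenitor or fibroblast-like nuclei made up 10.8% and 11.9%, mesothelial-like nuclei 9.58% and 7.12%, and macrophage-like nuclei 9.17% and 7.45%. Vascular endothelial-like nuclei made up 4.2% and 3.86%, T cell-like 3.59% and 3.04%, lymphatic endothelial-like 3.41% and 2.5%, dendritic-like 2.99% and 2.06%, and B cell-like 2.91% and 2.39%. Smooth muscle-like nuclei (0.60% and 0.46%), pericyte-like nuclei (0.70% and 0.61%), Schwann-like nuclei (0.27% and 0.34%) and natural killer or innate lymphoid-like nuclei (2.12% and 1.29%) were too few to compare. Nuclei of neighbouring organs were present, with pancreatic acinar-like nuclei at 0.78% and 2.40% and intestinal epithelial-like nuclei at 1.19% and 0.26%. The direction of the adipocyte share turned with the denominator: with unnamed cluster 5 left out (4.07% of control and 13.1% of cKO-labelled nuclei), the share was 43.7% in the control and 45.9% in the cKO-labelled library. Dissection and purification of nuclei can set such shares.

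**Figure D1:**
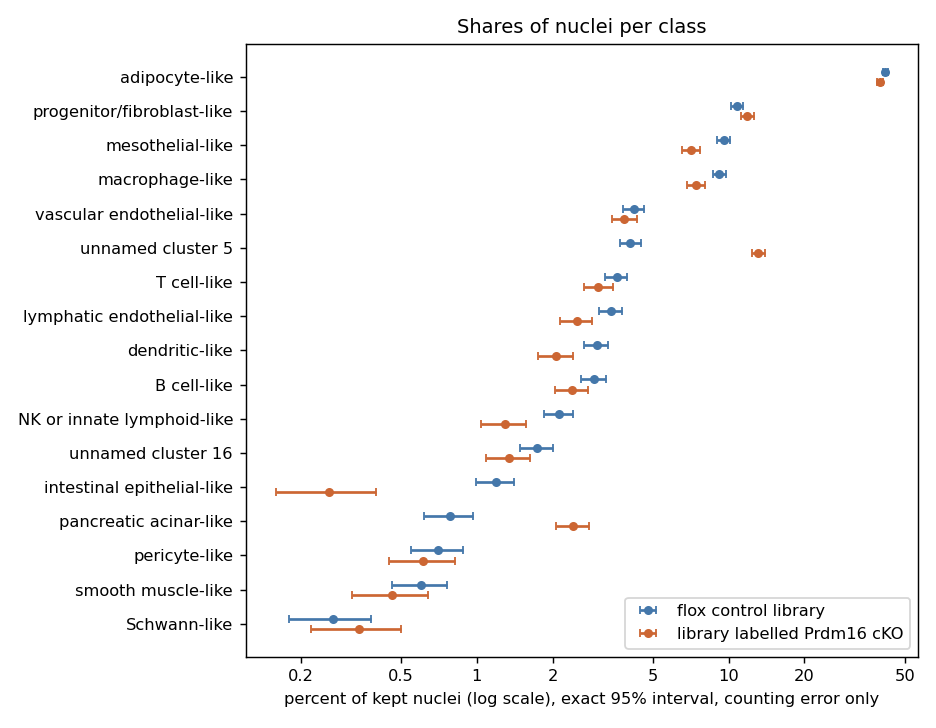
Percent of kept nuclei (horizontal axis) per class for the flox control library and the library labelled Prdm16 cKO, with exact Clopper-Pearson 95% intervals of counting error. Adipocyte-like nuclei were the largest class in both (41.9% and 39.9%), and unnamed cluster 5 made up 4.07% and 13.1%.

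Prdm16 (ENSMUSG00000039410, mm10 chromosome 4, 154316125 to 154636873) was not lower in adipocyte-like nuclei of the library labelled Prdm16 cKO. It had 966 UMIs and 16.6 CPM (15.6 to 17.7) in the control and 873 UMIs and 22.3 CPM (20.9 to 23.9) in the cKO-labelled library, a log2 ratio of 0.43 (0.29 to 0.56). Control adipocyte-like nuclei lay mostly in clusters 0 and 2 and cKO-labelled ones mostly in clusters 0 and 1. Within single clusters the log2 ratio ran from -0.40 in cluster 7, the smallest (649 and 228 nuclei), to 0.49, with no intervals computed. The levels in adipocyte-like nuclei were close to those of T cell-like nuclei (15.7 and 13.9 CPM) and B cell-like nuclei (11.0 and 14.7 CPM). Adipocyte markers stood at 35.7% and 28.2% of their adipocyte level in control T and B cell-like nuclei. Adipocyte RNA would thus give only part of Prdm16 there. The level in adipocyte-like nuclei did not stand out from these classes, so its ratio says little about Prdm16 made in adipocytes. The labels do not give the floxed exon, so counts over the 3' end of the transcript need not cover the deleted part and leave the labels unchecked. The highest levels lay outside adipocytes. Vascular endothelial-like nuclei had 378 CPM in the control and 207 CPM in the cKO-labelled library, a log2 ratio of -0.87 (-1.05 to -0.70), or -0.53 (-0.71 to -0.36) after the adipocyte profile was subtracted. This class pooled clusters 10 and 18, within which no values were computed. Smooth muscle-like nuclei had 309.6 and 341 CPM, pancreatic acinar-like nuclei 252 and 302 CPM, Schwann-like nuclei 292 and 184 CPM, and intestinal epithelial-like nuclei 115 and 133 CPM.

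**Figure D2:**
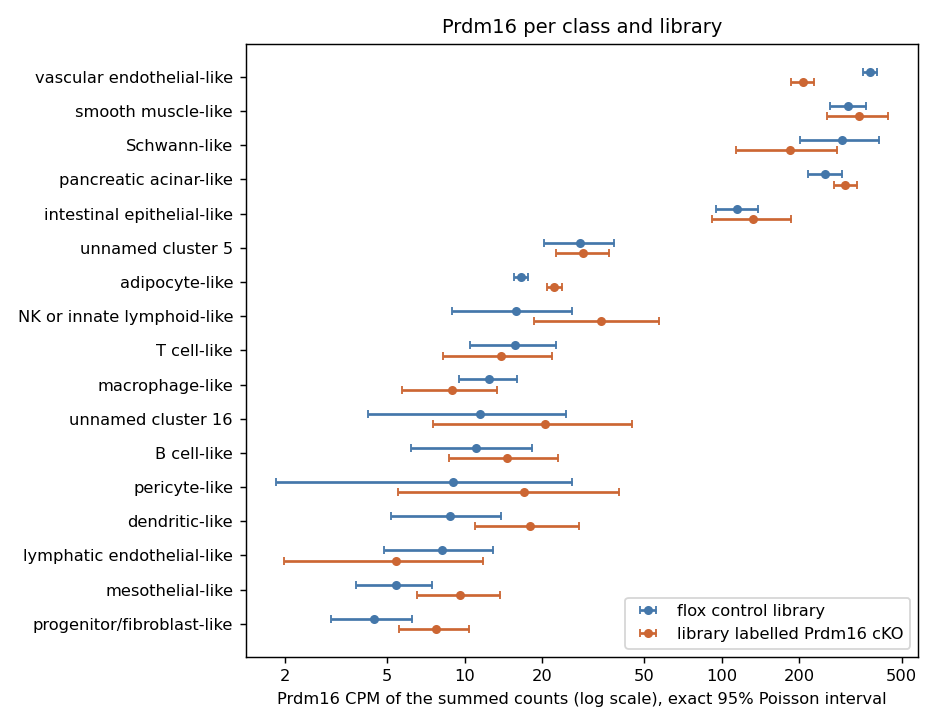
Prdm16 in CPM of the summed counts (log axis) per class for the flox control library and the library labelled Prdm16 cKO, with exact 95% Poisson intervals. Vascular endothelial-like nuclei (378 and 207 CPM) and smooth muscle-like nuclei (309.6 and 341 CPM) lay far above adipocyte-like nuclei (16.6 and 22.3 CPM).

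Ucp1, the uncoupling protein of thermogenic fat (chromosome 8, 83290352 to 83298452), was at or below the detection limit in adipocyte-like nuclei of both libraries, with 1 UMI in the control and 0 in the cKO-labelled library. After thinning to 1000 UMIs, 0 of 4415 control nuclei had a UMI, which allows up to 0.068%, and 0 of 2941 cKO-labelled nuclei, which allows up to 0.102%. Unthinned, the shares were 0.023% (0.001 to 0.126%) and 0%. B and T cell-like nuclei, which should lack the gene, had 0 of 684 and 0 of 396 (up to 0.439% and 0.758%), at median depths of 3725 and 3938 UMIs against 12108 and 11907 in adipocyte-like nuclei. The upper ends of the Ucp1 intervals in adipocyte-like nuclei were 0.10 CPM in the control and 0.09 CPM in the cKO-labelled library. The control thus had no measurable Ucp1 level that could fall. Cidea, a lipid droplet protein of brown fat (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785), was higher in the cKO-labelled library at 16.3 against 9.80 CPM, a log2 ratio of 0.73 (0.57 to 0.90), but within the adipocyte-like clusters taken alone it was -0.01 in cluster 0, 0.11 in cluster 1, -0.25 in cluster 2 and 0.11 in cluster 7. The adipokine gene Adipoq was lower at 235 against 284 CPM (-0.27, -0.31 to -0.23), but -0.08 in clusters 0 and 7 and 0.22 in cluster 2. Lep, which encodes leptin, was at 162 against 142 CPM (0.19, 0.15 to 0.24), with -0.03 in cluster 0, 0.35 in cluster 1 and -0.06 in cluster 2. Agt, which encodes angiotensinogen, was at 3.27 against 3.80 CPM, a difference not detectable at this depth (-0.22, -0.54 to 0.10), with 1.15 in cluster 1, 0.18 in cluster 7 and -0.27 in cluster 2. Qsox1, a sulfhydryl oxidase of the extracellular matrix, was at 52.3 against 48.8 CPM (0.10, 0.02 to 0.18), and at -0.12 after thinning, -0.13 in cluster 1 and -0.03 in cluster 7. The angiotensin receptor gene Agtr1a had 6 and 4 UMIs in smooth muscle-like nuclei (0.99, -1.28 to 3.07), too few to show a difference. In pericyte-like nuclei, looked up after the data were seen, it was at 637 CPM in the control and 452 CPM in the cKO-labelled library (-0.49, -0.82 to -0.18). Adipocyte markers in pericyte-like nuclei stood at 27.3% of their adipocyte level in the control and 55.1% in the cKO-labelled library, and with the adipocyte profile subtracted the log2 ratio of Agtr1a turned to 0.20 (-0.12 to 0.52), so no direction is read.

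Of the genes named as higher in cKO-labelled adipocyte-like nuclei, Angptl8 and Ppp1r3b were the highest. Angptl8, a feeding-induced regulator of lipoprotein lipase (ENSMUSG00000047822, chromosome 9, 21835510 to 21837347), was 3.37 times higher (17.3 to 58.3 CPM, log2 ratio 1.75, 1.65 to 1.86). Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1 (ENSMUSG00000046794, chromosome 8, 35375739 to 35388139), was 2.99 times higher (65.9 to 197 CPM, 1.58, 1.52 to 1.64). Acly, which makes cytosolic acetyl-CoA from citrate, was at 738 and 1643 CPM (1.15, 1.14 to 1.17), and the mitochondrial citrate carrier Slc25a1 at 49.8 and 105 CPM (1.07). Fasn, the fatty acid synthase, was at 352 and 706 CPM (1.00, 0.98 to 1.03), the desaturase Scd2 at 48.9 and 97.9 CPM (1.00), and the elongase Elovl6 at 662 and 1321 CPM (1.00). The others of the 12 highest were Zfp949 (1.51), Pgm3 of the hexosamine pathway (1.17), the metalloreductase Steap4 (1.07), Prune2 (1.04) and Dipk1b (1.03). Within the adipocyte-like clusters taken alone, 9 of these 12 were higher in every cluster, while Acly (-0.05), Elovl6 (-0.23) and Prune2 (-0.67) were lower in cluster 0. Elovl6, Acly, Pgm3, Ppp1r3b, Dipk1b and Prune2 were among the genes that defined cluster 1. That cluster held 17.8% of control and 45.6% of cKO-labelled adipocyte-like nuclei. Within clusters, Angptl8 lay between 0.91 and 1.66, Ppp1r3b between 0.34 and 1.09, and Fasn between 0.31 and 0.86, while in cluster 0 Pgm3 was at 0.03, Dipk1b at 0.17 and Scd2 at 0.24, and in cluster 1 Elovl6 was at 0.03.

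The lowest of the 12 lower genes under the naming rule was Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), at 36.2 CPM in the control and 16.9 CPM in the cKO-labelled library (-1.10, -1.23 to -0.98). Angptl4, a fasting-induced inhibitor of lipoprotein lipase, was at 50.6 and 26.9 CPM (-0.91, -1.01 to -0.81), and was lower in each of the 4 adipocyte-like clusters. The neurotrophin receptor gene Ntrk2 was at 144 and 76.1 CPM (-0.92), the prostaglandin-degrading Hpgd at 55.8 and 30.5 CPM (-0.87), and the transcriptional repressor Bcl6 at 306 and 169 CPM (-0.86). Vsir, an immune checkpoint gene (-0.83), Olfr1033 (-0.83), Trim67 (-0.82), the cell adhesion gene Kirrel (-0.82), the imprinted gene Peg3 (-0.80), Folh1 (-0.79) and the desmosomal Pkp2 (-0.78) followed. Of these 12, 7 were lower in every cluster, but Bcl6 lay between -1.45 in cluster 2 and -0.09 in cluster 1, Ntrk2 was at -0.17 in cluster 1, and Angptl4 at -0.24 and Trim67 at -0.29 in cluster 2. Hpgd (0.05) and Kirrel (0.01) were not lower in cluster 1, where Olfr1033 was level at 0.00, nor was Peg3 in cluster 0 (0.17), nor Folh1 in clusters 0 and 2 (0.13 and 0.03). Peg3 was among the genes that defined cluster 2, which held 35.6% of control and 9.04% of cKO-labelled adipocyte-like nuclei.

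As a group, de novo lipogenesis stood furthest apart in adipocyte-like nuclei: all 14 members were higher in the cKO-labelled library, 10 of them at least 1.5 times, with a median log2 ratio of 0.82 at percentile 100 of random lists. Pnpla3 (0.36) and Elovl5 (0.47) differed least. The median was 0.11 in cluster 0, 0.33 in cluster 1, 0.44 in cluster 2 and 0.54 in cluster 7. In cluster 0 it lay below that of oxidative phosphorylation, which was at least 0.16 in each cluster. The ranking is thus that of the pooled adipocyte-like nuclei. Genes of oxidative phosphorylation were also higher, with 20 of 20 members above 0 and a median of 0.25 (percentile 99.98; 0.16 in clusters 2 and 7), from Cycs (0.71) and Atp5b (0.57) to Uqcrc2 (0.09) and Ndufv1 (0.03). The insulin and feeding list had a median of -0.20 (percentile 0.02), or -0.11 after thinning and -0.10, -0.05, -0.11 and -0.18 in clusters 0, 1, 2 and 7, with members far apart: the insulin-regulated glucose transporter gene Slc2a4 (0.86, 28.8 to 52.3 CPM) and hexokinase Hk2 (0.69) were higher, and Angptl4 and the fasting-induced kinase Pdk4 (-0.71) were lower. Triglyceride storage had 8 of 13 members higher and a median of 0.11 (percentile 97.56; 0.00 in cluster 0), with Agpat2 (0.42) and Gpam (0.37) highest and Fabp4 (-0.42) and Cidec (-0.38) lowest. Lipolysis had 5 of 12 members higher and a median of -0.07 (percentile 20.2), or 0.03 after thinning, with Adrb1 (0.62) and G0s2 (0.59) against Aqp7 (-0.67). Fatty acid oxidation lay at 0.01 (percentile 69.0), or -0.03 with TMM scaling, with 8 of 15 members higher, among them Acadvl (0.34) and Slc25a20 (0.24), and with Cpt1a (-0.39) and Acadl (-0.30) lowest.

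The thermogenic list, the group tied most closely to Prdm16, was not lower. Of its 20 measured members 14 were higher and 6 lower, with a median of 0.18 at percentile 97.7, but -0.01 in cluster 0, -0.02 in cluster 1, 0.11 in cluster 7 and 0.05 after thinning. Ucp1 had too few UMIs to be among the measured members. Acot11 (1.07) and Cox8b (1.01) were highest and Pdk4 (-0.71) and Tnfrsf9 (-0.23) lowest. Genes of heat production without Ucp1 had 5 of 8 members higher and a median of 0.05 (percentile 48.4), with Gatm of creatine synthesis at 1.10 and 5.39 CPM (2.29), Pm20d1 at 0.46, Alpl at -0.20 and Slc6a8 at -0.04. Gatm was higher in B cell-like nuclei as well (3.08, 3 and 23 UMIs), in the library where pancreatic acinar-like nuclei were more frequent (2.40% against 0.78%). The median of this Ucp1-independent heat list was 0.47 after thinning and 0.69 in cluster 7 and turned to -0.05 with the mean of CPM per nucleus. The white-selective list had 5 of 10 members higher and a median of 0.05 (percentile 67.1; -0.08 after thinning and 0.28 in cluster 1), with Igfbp3 (0.66) and Hoxc9 (0.26) against Mest (-1.07) and Sncg (-0.69). Known binding partners of Prdm16 had 7 of 9 members higher and a median of 0.10 (percentile 84.6; -0.01 in cluster 2), with Pparg, the adipocyte master regulator, at 2562 and 3136 CPM (0.29), Ctbp2 at 0.29, Mecom at -0.15 and Ebf2 at -0.03.

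**Figure D3:**
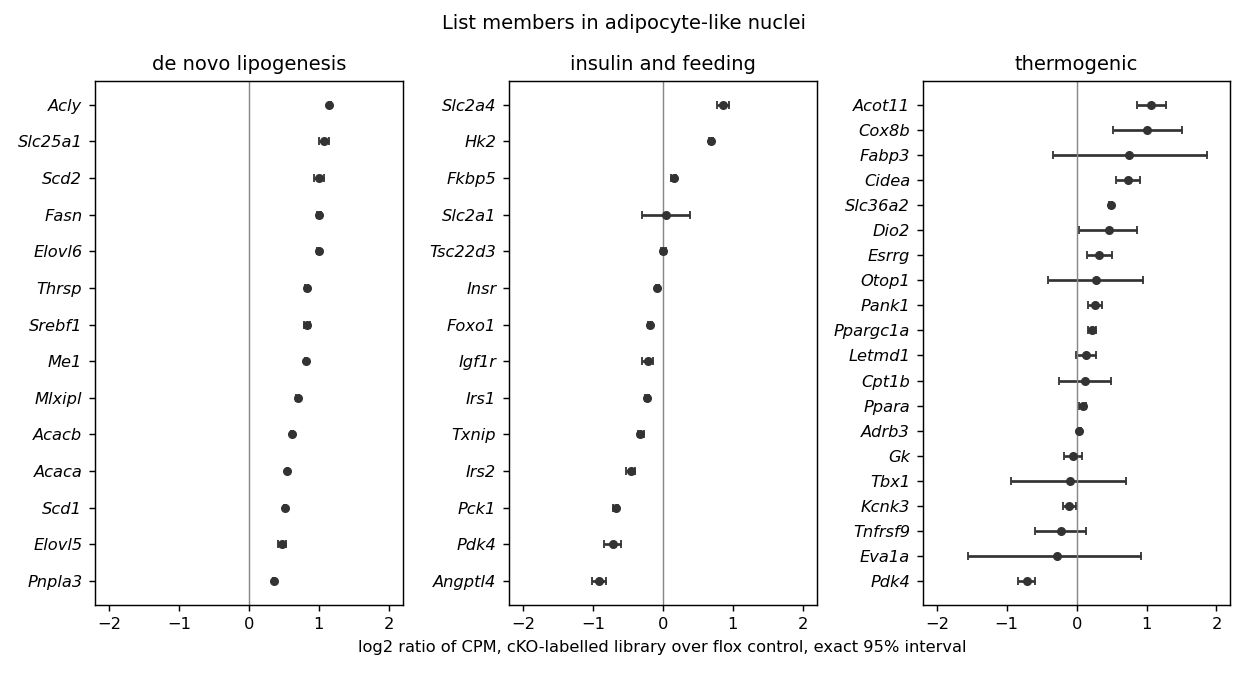
Log2 ratio of CPM (horizontal axis), cKO-labelled library over flox control, in adipocyte-like nuclei for each measured member of the de novo lipogenesis, insulin and feeding, and thermogenic lists, with exact 95% counting intervals. De novo lipogenesis had all 14 members above 0 (median 0.82), while the insulin and feeding list (median -0.20) and the thermogenic list (median 0.18) lay on both sides of 0.

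Among secreted and vascular groups in adipocyte-like nuclei, adipokine genes had 8 of 12 members higher and a median of 0.18 (percentile 97.45), or 0.07 with each library clustered on its own and 0.02 in cluster 2, with Apln (0.87) and Rbp4 (0.43) highest. Their lowest member, Itln1 (-2.84), is an intestinal gene, and intestinal epithelial-like nuclei were fewer in the cKO-labelled library (0.26% against 1.19%). The renin-angiotensin list had 4 of 8 members higher and a median of 0.09 (percentile 69.6), or -0.11 with each library clustered on its own, with Ace at 0.42, Enpep at 0.27 and Agt as given above. Vasoactive genes had 8 of 15 members higher and a median of 0.06 (percentile 63.0), or -0.04 with the mean of CPM per nucleus, with Cbs of hydrogen sulfide synthesis (1.00) and Nos3 (0.39) highest, and Tbxas1 (-0.28) and the natriuretic peptide clearance receptor gene Npr3 (-0.77, 818 to 481 CPM) lowest. Npr3 was among the genes that defined cluster 2, which held 35.6% of control and 9.04% of cKO-labelled adipocyte-like nuclei. Its ratio within single clusters was not computed. Angiogenic genes had 7 of 11 higher and a median of 0.15 (percentile 95.3), or -0.00 in cluster 1, from Vegfa (0.50, 274 to 388 CPM) and Angpt2 (0.26) to Fgf2 (-0.31) and Pdgfd (-0.41). Endothelial activation lay at 0.24 (percentile 89.3) with 6 of 8 higher, led by Icam1 (0.45) and Vcam1 (0.39), and with Vwf at -0.22. The endothelial activation median turned to -0.29 after thinning and -0.13 in cluster 7, and was 0.55 with 10% free RNA subtracted. Endothelial homeostasis lay at -0.05 (percentile 9.29), or 0.14 with 10% free RNA subtracted, with 6 of 14 higher, from Sox17 (0.47) and Nos3 to Cd36 (-0.23) and Fabp4. The endothelial lists hold markers of another cell type, such as Vwf, so their counts in adipocyte-like nuclei may be free RNA. Vascular tone genes lay at 0.05 (percentile 42.1), or -0.13 after thinning, with 13 of 20 higher, from Trpc6 (0.63) and Agtr1a (0.18) to Pde3a (-0.40) and Gucy1a1 (-0.49).

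Structural genes of the extracellular matrix were lower in adipocyte-like nuclei by a small amount, with 13 of 23 members lower and a median of -0.11 (percentile 0.68), which turned to 0.01 in cluster 0, 0.04 in cluster 1 and 0.03 with 10% free RNA subtracted. The thrombospondins Thbs2 (-1.63, 7.50 to 2.43 CPM) and Thbs1 (-1.49, 8.10 to 2.89 CPM) were lowest and Col14a1 (0.42) and Col6a1 (0.23) highest. Matrix remodelling genes had 13 of 20 higher and a median of 0.08 (percentile 50.8), or -0.07 in cluster 7, from Loxl1 (0.58) and Mmp2 (0.51) to Adamts2 (-0.40) and the cross-linking enzyme Lox (-0.70). The TGF-beta and BMP list lay at -0.04 (percentile 21.4), or 0.01 after thinning, with 11 of 23 higher, with Ltbp2 (0.69) and Bmp7 (0.53) highest and Acvr1c at -0.40. Smooth muscle contractile genes lay at -0.31 (percentile 0.02), with 8 of 13 lower, among them Acta2 (-1.18) and Synpo2 (-0.71), and with Tagln (0.76) and Itga8 (0.38) highest. These are markers of another cell type, and the median turned to 0.02 and 0.45 with 5% and 10% free RNA subtracted. Smooth muscle synthetic genes lay at 0.05 (percentile 55.0), or -0.19 in cluster 7, with 9 of 14 higher, from Mgp (0.56) and Vcam1 to Klf5 (-0.80) and Thbs1.

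In adipocyte-like nuclei, inflammatory genes had 11 of 12 members higher and a median of 0.27 (percentile 87.4), from Saa3 (0.99) and Icam1 to Cxcl10 (0.03) and Csf1 (0.02). The inflammatory median turned to -0.20 after thinning and in cluster 7, and was 0.05 with doublets kept and 0.45 with 10% free RNA subtracted. Interferon genes had 15 of 23 higher and a median of 0.08 (percentile 50.2), or -0.01 in cluster 0, from Irf7 (0.83) and Irf9 (0.34) to Rsad2 (-0.40) and Ifit2 (-0.58). The unfolded protein response lay at 0.11 (percentile 89.8), or 0.00 in cluster 0 and 0.29 in cluster 7, with 7 of 9 higher, from Xbp1 (0.49) and Herpud1 (0.38) to Pdia4 (-0.43) and Trib3 (-0.53). Immediate early genes lay at -0.05 (percentile 22.9), or 0.18 after thinning, with 7 of 12 lower, from Ier3 (0.57) and Nr4a1 (0.43) to Fos (-0.35) and Atf3 (-0.80). Interstitial progenitor markers lay at 0.24 (percentile 91.1), or 0.01 after thinning and -0.07 in cluster 2, with 6 of 9 higher, from Efhd1 (0.42) and Ly6c1 (0.26) to Dpp4 (-0.11) and Cd55 (-0.25), and committed preadipocyte markers at -0.06 (percentile 24.1) with 4 of 10 higher, from Apoe (0.51) and Icam1 to Fabp4 and Zfp423 (-0.42). Interstitial progenitor markers such as Dpp4 belong to another class, so their counts here may be free RNA. Cell cycle genes lay at -0.03 (percentile 21.8), or 0.16 in cluster 7, with 5 of 10 higher, from Cenpe (0.13) and Mki67 (0.09) to Top2a (-0.40) and Cenpf (-0.43). RNA quality genes lay at -0.08 (percentile 7.29), or 0.19 in cluster 7, with 9 of 15 lower, from Rps2 (0.55) and Rpl13 (0.34) to mt-Nd2 (-0.23) and mt-Nd5 (-0.35). This list mixes the nuclear RNAs Malat1 and Neat1 with mitochondrial, ribosomal protein and translation genes. Malat1 (0.04 to 0.28) and Neat1 (0.12 to 0.52) were higher in every class compared. A lower median of the list therefore need not mean poorer RNA, here or in the other classes. Sex-linked genes lay at 0.03 (percentile 77.3): the Y-linked Uty (450 and 436 CPM) and Kdm5d (89.9 and 89.0 CPM) were present in both libraries at like levels, while Xist was at 1.20 and 1.56 CPM (0.37) and the antisense Tsix, which overlaps it and cannot be told from it without strand, at 0.77.

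Core clock genes differed between the libraries in adipocyte-like nuclei and in most other classes. The circadian list had a median of 0.25 in adipocyte-like nuclei (percentile 99.92) with 10 of 15 members higher, led by the PAR bZIP factor gene Dbp (0.68) and the period gene Per3 (0.49). Within the adipocyte-like clusters taken alone the circadian median was lower, at 0.04 in cluster 0, 0.10 in clusters 1 and 7 and -0.09 in cluster 2. Npas2, a partner of BMAL1 (chromosome 1, 39193731 to 39363236), was at 22.0 and 4.83 CPM (-2.19, -2.42 to -1.97), and Arntl was lower as given above. Arntl was lower in 8 of the 9 classes, from -0.51 in macrophage-like and T cell-like nuclei to -1.38 in vascular endothelial-like nuclei, the exception being B cell-like nuclei (0.05, -0.33 to 0.43), and in T cell-like nuclei it was at -0.02 after subtraction. Npas2 was lower in all 9, from -0.72 (-1.66 to 0.14) in lymphatic endothelial-like nuclei to -3.53 in vascular endothelial-like nuclei (39.3 to 3.41 CPM). In progenitor or fibroblast-like nuclei, where both were better counted, Arntl was at 108 and 55.5 CPM (-0.96) and Npas2 at 103 and 45.0 CPM (-1.19). Per3 was higher in all 9 classes (0.49 to 1.10), as was Dbp (0.67 to 1.38). Per2 was higher in 6 classes, while its intervals included 0 in macrophage-like (-0.17 to 0.52), vascular endothelial-like (-0.07 to 0.64) and lymphatic endothelial-like nuclei (-0.09 to 1.10). Clock itself lay between -0.43 and 0 in the 9 classes. The list median in B cell-like nuclei was 0.43, and -0.31 with the adipocyte profile subtracted.

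**Figure D4:**
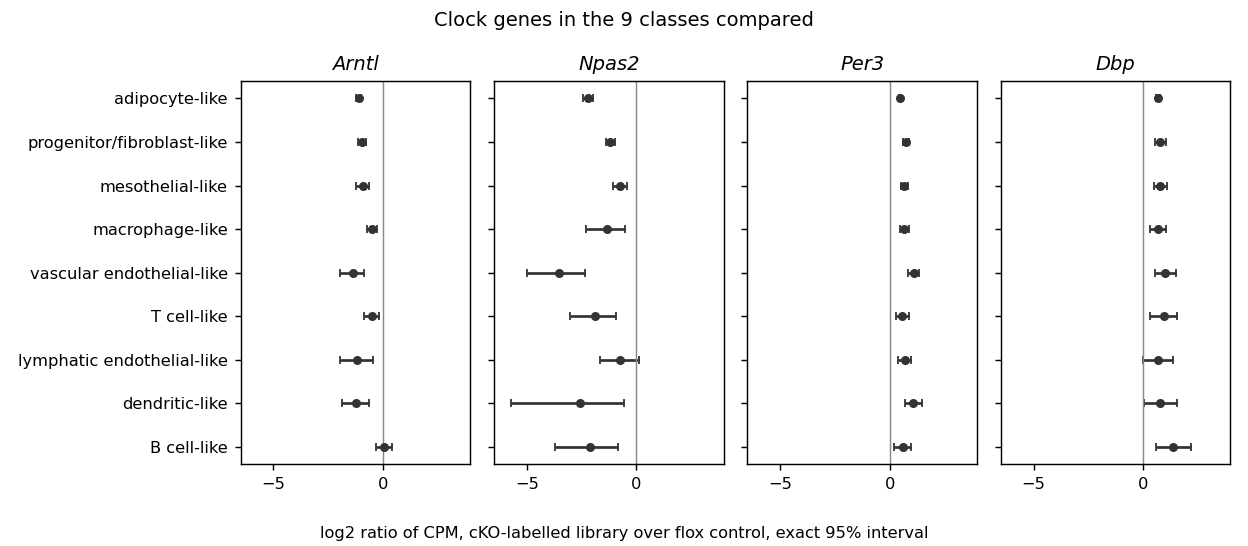
Log2 ratio of CPM (horizontal axis), cKO-labelled library over flox control, for Arntl, Npas2, Per3 and Dbp in each of the 9 classes compared, with exact 95% counting intervals. Npas2 was below 0 in all 9 classes and Arntl in 8, while Per3 and Dbp were above 0 in all 9.

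Lipogenesis genes were higher in the cKO-labelled library outside adipocytes too, and so was adipocyte RNA. The median log2 ratio of de novo lipogenesis ran from 0.86 in progenitor or fibroblast-like nuclei to 1.29 in vascular endothelial-like nuclei, at percentile 100 in all 8 other classes. In these classes adipocyte markers stood at 19.0 to 35.7% of their adipocyte level in the control and 23.1 to 54.6% in the cKO-labelled library, higher in the latter in all 8. With the adipocyte profile subtracted, the lipogenesis medians were 0.65 in progenitor or fibroblast-like, 0.84 in mesothelial-like, 0.88 in macrophage-like, 0.94 in lymphatic endothelial-like, 0.62 in vascular endothelial-like, 0.40 in dendritic-like, 0.39 in T cell-like and 0.04 in B cell-like nuclei, over 6 to 12 members each. Members left with no counts in 1 or both libraries after subtraction were left out of these medians. The medians thus omit genes that adipocyte RNA could account for, and do not show that the list as a whole stayed higher. Summed over the 8 other classes, Acaca, Acly, Elovl6 and Me1 had no computable value after subtraction, while Fasn was at 1.07 and Scd1 at 0.67. Genes named in these classes that adipocytes carry at a higher level, such as Angptl8 and Ppp1r3b, stand beside this difference in adipocyte RNA.

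Progenitor or fibroblast-like nuclei had lower structural matrix genes in the cKO-labelled library. Cilp, a cartilage matrix protein gene (33.3 to 15.1 CPM, -1.14, -1.52 to -0.77), Col6a5 (26.9 to 12.7 CPM, -1.08) and the basement membrane collagen gene Col4a3 (52.0 to 27.9 CPM, -0.90) were, with Npas2 and Arntl, the 5 lowest of the genes that the naming rule took in this class, with log2 ratios of -1.08, -1.03 and -0.84 after subtraction. Of 23 structural matrix genes 17 were lower, 3 of them at least 1.5 times, with a median of -0.21 (percentile 0.00) and -0.14 after subtraction. Elastin (Eln) was at 493 and 310.0 CPM (-0.67), fibrillin-1 (Fbn1) at 2091 and 1438 CPM (-0.54), Thbs2 at -1.20 and Thbs1 at -0.91, while Bgn (0.47) and Lum (0.19) were highest. Matrix remodelling genes were not lower in progenitor or fibroblast-like nuclei, with 10 of 20 higher and a median of -0.00 (percentile 38.2; 0.02 after subtraction). Tgfb3, a TGF-beta ligand gene, was at 35.2 and 20.8 CPM (-0.76). Immediate early genes were lower in 10 of 12 cases (median -0.33, percentile 0.08), with Ier2 at -0.75 and Jun at -0.68, and the median of immediate early genes in progenitor or fibroblast-like nuclei was -0.72 after thinning. RNA quality genes had a median of -0.14 in this class. Interstitial progenitor markers (-0.11, percentile 10.4) and committed preadipocyte markers (0.04, percentile 84.6) lay within the range of random lists. Zfp949 (1.78), Angptl8 (1.88), Ppp1r3b (1.68), Slc2a4 (1.58) and Acly (1.23) were the 5 highest under that rule, and the last 4 were higher in adipocytes than here. Among genes at least as high here as in adipocytes, Synpr (1.11) and Pcdh11x (0.85) followed Zfp949.

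Mesothelial-like nuclei had lower immediate early genes in the cKO-labelled library: 11 of 13 were lower, 6 at least 1.5 times, with a median of -0.56 (percentile 0.00) and -0.57 after subtraction, or -0.21 after thinning and -0.31 with list members with at least 1 UMI. Fos, a subunit of AP-1, was at 12.3 and 3.10 CPM (-1.99) and Atf3 at 17.5 and 6.21 CPM (-1.5). Nr4a3, an orphan nuclear receptor gene with immediate early induction, was at 27.3 and 6.21 CPM (-2.14, -2.88 to -1.47). RNA quality genes were lower here as well, with a median of -0.28, and the median mitochondrial share of UMIs was 0.671% in the control and 0.503% in the cKO-labelled library. Trim12a (-2.43) and Arntl (-0.91) were the other named lower genes. Zfp949 (1.99), Ppp1r3b (1.5), Sh2b2 (1.33), Gpd1 (1.24) and Fasn (1.19) were the highest under the naming rule, and all but Zfp949 were higher in adipocytes than here. Among genes at least as high here as in adipocytes, Tcea3 (1.15) and the collagen gene Col6a6 (1.11, 13.6 to 29.5 CPM) were higher. Macrophage-like nuclei differed in few genes of their own. Trim30d was lower (24.9 to 9.69 CPM, -1.36), and Zfp949 (2.01), Rhof (1.92), Dipk1b (1.81), Angptl8 (1.79) and Pgm3 (1.5) were higher. These higher genes all had a lower CPM here than in adipocyte-like nuclei. After subtraction Zfp949 was at 2.23 and Angptl8 at 1.61 (0.26 to 3.15), and no value could be computed for Rhof, Dipk1b and Pgm3. Of genes at least as high here as in adipocytes, Zc3h12a, which encodes the RNase regnase-1 (1.23, 8.59 to 20.1 CPM), and Erc2 (1.42) were higher. Interferon genes (0.00, percentile 64.0) and inflammatory genes (0.21, percentile 69.7; -0.26 after thinning) in macrophage-like nuclei lay within the range of random lists.

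Vascular endothelial-like nuclei, taken as 1 class, had lower levels of a set of genes that included Prdm16. The class pooled clusters 10 (341 and 228 nuclei) and 18 (101 and 57 nuclei), and no values were computed within them. Lower levels per nucleus were therefore not told apart from a different mix of endothelial nuclei. Dkk2, a modulator of Wnt signalling, was at 87.3 and 18.7 CPM (-2.22, -2.79 to -1.69; 34 and 15 nuclei with a UMI), Arhgap20 at -1.84, the interleukin-13 receptor gene Il13ra1 at -1.82, the magnesium channel gene Trpm6 at -1.81 and Tox2 at -1.78. After subtraction these 5 lay between -1.41 and -1.84. Eln was at 1374 and 787 CPM (-0.80), the lymphangiogenic factor gene Vegfc at 536 and 310.0 CPM (-0.79), the angiopoietin receptor gene Tek at -0.73, and Ccn2 at -1.19, which shrank after subtraction to -0.42 for Eln, -0.41 for Vegfc, -0.35 for Tek and -0.85 for Ccn2. Interferon genes were lower in 18 of 22 cases (median -0.37, percentile 0.04; -0.22 after subtraction, -0.14 with each library clustered on its own, -0.06 with list members with at least 100 UMIs), with Oasl2 at 48.4 and 21.0 CPM (-1.20; -0.90 after subtraction) and Ifi44 at -0.97 (-0.60) against Rtp4 (0.71) and Ifi27 (0.51). Endothelial activation genes had a median of -0.44 (percentile 0.94), with Selp at -0.60 and Edn1, the endothelin gene, at -0.57, but after subtraction the median was -0.03, Selp at -0.22 and Edn1 at -0.19. Adipocyte markers in this class stood at 24.0% of their adipocyte level in the control and 41.9% in the cKO-labelled library, and RNA quality genes had a median of -0.39. Angptl8 (2.33), Robo2 (2.09), Slc25a1 (1.82), Acly (1.82) and Cd27 (1.81) were the highest under the naming rule, and all but Robo2 were higher in adipocytes than here.

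The smaller classes had few UMIs and some of their named genes came from a handful of nuclei. Lymphatic endothelial-like nuclei had lower Ncam2, a neural cell adhesion gene (945 to 363 CPM, -1.38, -1.54 to -1.22; -1.26 after subtraction), Itgb8 (-1.77), Ube2ql1 (-1.76), Clcc1 (-1.67) and Pqlc1 (-1.5). Their higher genes were Unc5c (4.41, from 10 nuclei in the control and 4 in the cKO-labelled library), Ano4 (2.58, 6 and 2 nuclei), Angptl8 (2.19), Dipk1b (2.06) and Hs6st3 (1.81, 12 and 5 nuclei). Angptl8 and Dipk1b were higher in adipocytes than in lymphatic endothelial-like nuclei. Dendritic-like nuclei had lower Runx2, a transcription factor gene (142 to 46.7 CPM, -1.60), Basp1 (-1.73), Mctp2 (-1.70), Ankdd1a (-1.68) and Dscam (-1.54, 9 and 5 nuclei), and higher Cyp7b1 (3.22, 10 and 11 nuclei), Zfp949 (2.01), Skint3 (1.82), Fscn1 (1.77, 8 and 4 nuclei) and tissue factor F3 (1.66). F3 was higher in adipocytes than in dendritic-like nuclei and had no computable value after subtraction. T cell-like nuclei had lower Trim12a (63.4 to 6.16 CPM, -3.36), Klrc1 (-2.11, 25 and 6 nuclei), Elavl4 (-2.11), Klrb1b (-2.0) and Klrb1f (-1.53). In the same order, these were at -3.21, -1.62, -1.67, -1.52 and -1.04 after subtraction. Klrb1b and Klrb1f belong to a family of similar genes, so their counts are uncertain. Angptl8 (2.59), Bcl2l2 (2.02), Ppp1r3b (2.0), Pgm3 (1.99) and Sycp3 (1.94) were higher. None of these higher genes had a computable value after subtraction. Adipocyte markers in T cell-like nuclei stood at 35.7% of their adipocyte level in the control and 54.6% in the cKO-labelled library. B cell-like nuclei had lower Agbl1 (673 to 208 CPM, -1.69), Mageb18 (-3.00), St18 (-2.54, 10 and 6 nuclei), Trim12a (-2.19) and immunoglobulin Igha (-2.02, 11 and 9 nuclei), and higher Nr6a1os (2.18), Ppp1r3b (2.11), Zfp949 (2.04) and Dipk1b (1.94). After subtraction Agbl1 was at -1.24, St18 at -2.26, Trim12a at -1.84 and Igha at -1.59 in B cell-like nuclei. No value could be computed there for Mageb18, Nr6a1os, Ppp1r3b and Dipk1b. Cell cycle genes in B cell-like nuclei had a median of 0.54 (percentile 99.2), which was 0.15 with list members with at least 1 UMI, 1.26 with doublets kept and 0.98 after subtraction, with the topoisomerase gene Top2a at 15.5 and 54.5 CPM from 8 and 12 nuclei. RNA quality genes had medians of -0.71 in B cell-like, -0.53 in dendritic-like, -0.33 in T cell-like and -0.12 in lymphatic endothelial-like nuclei.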

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

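Both tests of unnamed cluster 5 below were set before their results were seen, the comparison with depth was made after, and nothing else in this part was tested. Pancreatic acinar-like nuclei, which enter no comparison of the results, made up 2.40% (2.06 to 2.78%) of cKO-labelled nuclei and 0.78% (0.62 to 0.97%) of control nuclei. They stood out because the share in the cKO-labelled library lay above that in the control.

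Unnamed cluster 5, which enters no comparison either, made up 13.1% (12.4 to 13.9%) of cKO-labelled nuclei against 4.07% (3.70 to 4.47%) of control nuclei, at median depths of 2014 and 2043 UMIs. Droplets that hold mostly free RNA of the library are a candidate explanation: the markers of all 9 classes lay between 0.88 and 1.89 times their level in the other kept nuclei, and 0 classes lay outside 0.5 to 2 times in both libraries. Adipocyte nuclei that had lost RNA cannot be told apart from this: the markers of the 8 other classes stood at a median of 6.65 times (control) and 6.90 times (cKO-labelled) their level in adipocyte-like nuclei. The bound of 2 set against them was wrong, because a nucleus that lost its own RNA and kept the same free RNA would show these markers higher by the ratio of depths, 5.93 and 5.91 times. A biological difference between the genotypes stays open, since each genotype has 1 library.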

How the results depend on the processing

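The settings chosen after seeing the data were the single adipocyte-like clusters, the subtracted adipocyte profile (also for Agtr1a in pericyte-like nuclei) and the share without cluster 5, and all others were planned. Of the planned values, 986 lay within the counting interval of the reported value, 134 moved outside it and 4 reversed. Of the added ones, 102 stayed, 176 moved and 22 reversed. Reversed means a change of sign in a gene whose counting interval excluded 0, or in a list for which it did and whose median lay among the outer 5% of random lists. Changes of sign of any kind were more frequent, at 40 of the planned and 50 of the added values. The cause was not tested for any of them. Prdm16 in adipocyte-like nuclei lay between 0.35 and 0.49 under every planned setting. Within single clusters it ran up to 0.49, and it reversed to -0.40 in cluster 7. Cluster 7 was the smallest of the 4 (649 and 228 nuclei), and no interval was computed there. Median log2 ratios of de novo lipogenesis were 0.83 with doublets kept, 0.79 with each library clustered on its own, 0.78 with TMM and 0.77 with median-of-ratios scaling, and 0.11, 0.33, 0.44 and 0.54 in clusters 0, 1, 2 and 7. The thermogenic median was 0.05 after thinning to 1000 UMIs and reversed in cluster 0 (-0.01) and cluster 1 (-0.02). The adipocyte share was 48.7% and 44.4% (control, then cKO-labelled) under 1% mitochondrial UMIs, 40.2% and 38.0% with doublets kept and 43.7% and 45.9% without cluster 5, and the cKO-labelled share was 30.1% with each library clustered on its own. Thinning reversed Qsox1 (-0.12). Subtracting free RNA reversed the smooth muscle contractile list (0.02 at 5%, 0.45 at 10%) and the structural matrix list (0.03 at 10%), and subtracting the adipocyte profile reversed the circadian list in B cell-like nuclei (-0.31). Cluster 0 alone reversed Cidea (-0.01), Lep (-0.03), Acly (-0.05), Elovl6 (-0.23), Prune2 (-0.67), Peg3 (0.17), Folh1 (0.13) and the structural matrix list (0.01). Cluster 1 alone reversed Qsox1 (-0.13), Hpgd (0.05), Kirrel (0.01) and the structural matrix list (0.04). Cluster 2 alone reversed Cidea (-0.25), Adipoq (0.22), Lep (-0.06), Folh1 (0.03) and the circadian list (-0.09), and cluster 7 alone Qsox1 (-0.03). The share of adipocyte-like nuclei with Ucp1 lay between 0% and 0.023% under every setting, which left no level to compare. Depth limits the classes with few nuclei, where the size rule passed 67.2% of simulated 2-fold changes (vascular endothelial-like).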

Other observations

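The tests of clock genes, and for Eif4a2 those of adipocyte RNA and of Rfc4, were chosen after the data were seen, and the other tests of Eif4a2 were set before their results. The genes of this paragraph were chosen after their values were seen. Zfp949, a zinc finger gene on chromosome 9 (88548020 to 88571061), was higher in the cKO-labelled library in all 9 classes, with log2 ratios of 1.14 to 2.04. Trim12a, a tripartite motif gene on chromosome 7 (104299894 to 104315466), was lower in all 9 classes (-3.92 to -1.30), and its neighbour Trim30d lies at 104470014 to 104507849. The Trim12 and Trim30 genes are families of near-identical copies, so their counts are uncertain. The mitochondrial gene mt-Nd4l was lower in all 9 classes (-1.51 to -0.88). The pancreatic enzyme gene Cela1 was higher in all 9 classes, by 1.41 to 2.72, in the library where acinar-like nuclei were more frequent, and Prss2 in 8, the interval in T cell-like nuclei being -0.30 to 2.44.

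Arntl and Npas2 were lower and Per3 and Dbp higher in most classes, a pattern summed here as the mean log2 ratio of Per3 and Dbp less that of Arntl and Npas2. Adipocyte RNA carried into the other classes was argued against, because the contrast was 1.52 (1.36 to 1.69) over the 8 other classes with the adipocyte profile subtracted. A change confined to adipocyte-like nuclei, where Adipoq-Cre acts, was argued against as well: after subtraction the contrast lay above 0 in 5 of 5 classes, picked after the values were seen, the lowest being 1.33 in macrophage-like nuclei. Of the other classes, dendritic-like nuclei gave 4.50 (from 0.96), the interval in T cell-like nuclei started at -0.67, and none could be computed in B cell-like nuclei. Tissue taken at a different hour or feeding state remains a candidate explanation, with a contrast of 2.23 (2.10 to 2.37) in adipocyte-like nuclei, and cannot be told apart from genotype, because each genotype has 1 library and the labels give no hour.

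Eif4a2, a translation initiation factor gene on chromosome 16 (23107444 to 23114136) beside Adipoq (23146536 to 23158028), was higher in the cKO-labelled library in all 9 classes, by 0.47 to 0.82 on the log2 scale. It overlaps Rfc4 at its end, so its counts may include a few of that gene. A difference over the whole chromosome arm was argued against by a median of 0.06 over 152 genes lying 1 to 10 Mb from Adipoq, and adipocyte RNA by a log2 ratio of 0.56 (0.47 to 0.65) over the 8 other classes after subtraction. Extra copies of the segment carried with the Cre transgene cannot be told apart from a regulatory difference at this locus, as the ends of the segment are not given. Rfc4, which lies between, gave 0.51 (0.16 to 0.86) in adipocyte-like nuclei. Nuclei outside the compared classes gave 0.79 (0.66 to 0.92) for Eif4a2, a ratio within the range set beforehand for extra copies. That does not decide it, because a regulatory difference could give the same rise. These nuclei also carry adipocyte RNA, which was not subtracted from them here. Of other genes nearby, picked after their values were seen, Adipoq (-0.27), St6gal1 (-0.10), Dnajb11 (0.00) and Tbccd1 (-0.06) were not higher in adipocyte-like nuclei, while B630019A10Rik was (10.3 and 52.7 CPM, 2.36), as in 5 other classes (0.96 to 2.48), with intervals including 0 in T cell-like, B cell-like and vascular endothelial-like nuclei (-0.04 in the last).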
